A study of Mus musculus with 18 samples.

How the data were processed

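Poly(A)-enriched RNA was sequenced from cultures of 4T1, a transplantable mammary tumour line of BALB/c mice. There were 18 libraries in 6 groups of 3: parental cells in fresh medium, parental cells given 2 ng/mL recombinant TGFb1, and stable lentiviral lines carrying an empty vector (EV) or Wisp1, each grown on plastic and on collagen type I. RNA came from a column kit and libraries from a stranded mRNA kit, per the labels. The submitters' processing notes name CASAVA, BWA, STAR, HTSeq, limma and R 3.2.4 and the mouse build mm9, with no roles or order. The deposited values are raw counts per gene symbol, with no normalization by the authors. The gene annotation and the strand setting of the counting are not given in the sources used here. Because the reference annotation at hand is of another build, no coordinates are given. Counts for close paralogs (major histocompatibility, interferon-induced, keratin and histone genes) are uncertain, since the treatment of reads with several alignments is not stated and the summary entry for them was 0.

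Each library held 34591 gene symbols, none duplicated, and 10624 of them had no count anywhere. As a percentage of all counted reads of a library, reads outside genes came to 10.2 to 13.5%, ambiguous reads to 1.02 to 2.08% and reads without an alignment to 1.84 to 3.47%, and these entries were left out. Gene counts per library ran from 37552858 to 94401699. Replicates were cultures of the same parental or stable line, so p-values measure spread between cultures and not between independent transductions. Between-replicate chi-squared over its degrees of freedom was 3.109 to 219.6, above the counting error alone, and floors cover counting error only.

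Genes were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood F tests) in R 4.3.3. TGFb1 was compared with untreated cells in a fit of those 6 libraries, and the 12 libraries of the stable lines shared a fit with 4 group means, which gave Wisp1 against EV on each substrate, collagen against plastic in each line, and the interaction. A gene was called at an adjusted p (Benjamini-Hochberg, per comparison) under 0.05. Standard errors are the log2 change over the square root of F. CPM values are TMM-scaled over all 18 libraries and given as mean ± SD of 3 libraries.

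Gene lists of pathways, processes and cell-type markers were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated for each list and with fry. Lists needed 5 tested members; 29 lists met this in every comparison and the endothelial marker list did not. Adjusted p for a list is over the 29 lists of that comparison. The median, mean and test of each list past the threshold in a comparison of treatments or substrates had the same sign.

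Named genes were a panel (CCN family, TGF-beta ligands and targets, epithelial and mesenchymal genes), the 5 largest rises and falls with mean CPM of at least 5, no overlap between groups and a named symbol, and, for up to 6 pathway lists with the smallest camera p, up to 3 called members and 1 that moved the other way. For the interaction they were the 5 smallest p past the threshold. Comparisons, lists, panel, naming rule and most alternatives were set before the data were examined. Genes outside the rule are said to be chosen after their values were seen.

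Pairing by replicate number was checked by correlating deviations from the group means between libraries with the same number, with 0.1 as the minimum. The parental groups share codes in the labels, which do not say what the codes mark, and their 3 correlations were 0.79, 0.55 and 0.78. In the stable lines no label gives pairs. EV and Wisp1 correlated at 0.15, 0.25 and 0.28 on plastic and at 0.49, 0.17 and 0.36 on collagen. Plastic and collagen libraries of a line did not pass in every pair, at 0.13, −0.12 and 0.28 in EV and −0.04, −0.08 and −0.01 in Wisp1. A fit with the replicate number as a block, set in advance, was therefore run for TGFb1. For the stable lines a block over all 4 groups was also set in advance, and a block within each substrate was added after the correlations were seen. The block within each substrate rests on these correlations alone. Between substrates the EV libraries numbered 3 reached 0.28, as high as the highest on plastic. Beside a result, a blocked value is given only where it changed a call or moved a count by over 1.5 times.

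Detection was checked on simulated data: counts were drawn from negative binomial distributions with the means, dispersions and depths of the real libraries, and 200 genes were changed by known folds. Recovery at 1.2, 1.5, 2 and 4-fold was 0, 2, 20 and 77.1% for TGFb1 (14699 genes, without a block), 36, 68, 84 and 98% for Wisp1 on plastic, 44, 64, 88 and 98% on collagen, and 38, 68, 86 and 98% for collagen in EV. The false share of calls was 5.88, 5.92, 3.29 and 2.68% in that order. With the block within each substrate, recovery on plastic was 69.4, 74, 90 and 100% and the false share 8.29%. Those draws took their dispersions from the blocked fit and held no differences between pairs, so they cannot show whether the pairing is real.

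The alternatives were DESeq2 1.42.0, limma-voom, size factors of DESeq2's kind in edgeR, library totals only, no filter, a filter of 1 CPM in 3 libraries, a threshold of at least 2-fold, fits of all 18 libraries or only the 6 compared, replicate blocks, leaving out each library in turn, libraries thinned to equal totals, offsets for GC content and gene length, Wisp1 averaged over both substrates, and lists without Wisp1. The fit of all 18 libraries takes 1 spread per gene over 2 experiments of unlike spread. The biological coefficient of variation was 0.259 in the TGFb1 fit and 0.0641 in the stable-line fit.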

Results

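Gene expression was measured by poly(A) RNA sequencing in 18 cultures of the mouse mammary tumour line 4T1. Parental cells were left in fresh medium for 24 h (n = 3) or given 2 ng/mL TGFb1, a cytokine that drives matrix production and epithelial plasticity (n = 3). Stable lines with an empty lentiviral vector (EV) or with a vector for Wisp1, a secreted matricellular protein of the CCN family, were each grown on plastic (n = 3) and on collagen type I (n = 3). Gene counts per library were 74.26 to 83.57 M in untreated cells, 67.64 to 85.43 M with TGFb1, 41.76 to 77.75 M in EV and 37.55 to 59.57 M in Wisp1 on plastic, and 54.41 to 94.4 M in EV and 50.03 to 81.03 M in Wisp1 on collagen. Replicates correlated at 0.976 to 0.991 across genes in the parental groups and at 0.997 to 0.999 in the stable lines. The first principal component of 15032 genes held 55.5% of the variance and the second 13.7%.

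The first comparison asked what TGFb1 changed in parental cells. Wisp1 rose 18.7-fold, from 22.3 ± 16 to 425 ± 170 CPM (log2 change 4.23 ± 0.61 SE, n = 3 per group, adjusted p = 0.0096). The CCN family member Ctgf, a matricellular protein gene, rose 5.89-fold, from 117 ± 56 to 700 ± 360 CPM (adjusted p = 0.022). The largest rise was in Smoc1, which encodes a secreted calcium-binding matrix protein, at 68.8-fold (55.9 ± 30 against 0.802 ± 0.13 CPM, adjusted p = 0.0022). The largest fall was in the integrin gene Itga8, which was 18.9-fold lower (0.806 ± 0.075 against 15.1 ± 8.3 CPM, adjusted p = 0.0035). Of the other large rises, Prss46 rose 66.8-fold, Fank1 42.9-fold, the adaptor gene Sla 40.2-fold and the collagen gene Col27a1 25.9-fold. Mgp, an inhibitor of calcification, was 17.5-fold lower, Fer1l6 16.7-fold, the deiodinase gene Dio2 14.6-fold and the aldehyde dehydrogenase gene Aldh3a1 13-fold lower. Among CCN genes Cyr61 rose 2.39-fold (adjusted p = 0.028), Nov was 8.71-fold lower at low expression (0.214 ± 0.076 against 1.86 ± 0.69 CPM, adjusted p = 0.009), and Wisp2 was not called (adjusted p = 0.84). The feedback inhibitor Smad7 rose 2.79-fold, Tgfb2 3.8-fold, fibronectin (Fn1) 2.2-fold to 5890 ± 810 CPM, the repressor of epithelial genes Snai1 3.73-fold, and Col1a1 8.61-fold to 8.59 ± 6.7 CPM. Cdh1 (adjusted p = 0.97), Vim (0.74), Zeb1 (0.65) and Tgfb1 (0.85) were not called, and Lox was too low to test.

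Of 14874 genes tested after TGFb1, 1645 were called, 913 higher and 732 lower, and 858 of them by at least 2-fold. DESeq2 called 2910 and edgeR with all 18 libraries in one fit 4865. An unadjusted p under 0.05 was found for 3708 genes, or 7817 with the pairs as a block, where 744 were expected. Each called gene named above moved the same way in 3 of 3 pairs of libraries with the same code. With the pairs as a block, 6672 genes were called, 3326 higher and 3346 lower, all 1645 among them, and Epcam (1.21-fold lower, adjusted p = 0.0033 against 0.16) and Tgfb3 (adjusted p = 0.0044 against 0.14) passed the threshold. The count without the block fell to 380 without untreated replicate 2, 517 without TGFb1 replicate 2, 908 without untreated replicate 3, 981 without TGFb1 replicate 3 and 1018 without untreated replicate 1. Without untreated replicate 2 the adjusted p was 0.063 for Wisp1, 0.11 for Ctgf, 0.051 for Cyr61 and Smad7, 0.059 for Snai1, 0.17 for Col1a1, 0.054 for Prss46, 0.068 for Mgp, 0.053 for Fer1l6 and 0.11 for Aldh3a1. Without TGFb1 replicate 2 it was 0.072 for Ctgf and Mgp, 0.11 for Cyr61, 0.052 for Nov, 0.1 for Col1a1 and 0.14 for Aldh3a1. Cyr61 and Col1a1 also lost their calls without untreated replicate 1 (adjusted p = 0.052 and 0.055) and untreated replicate 3 (0.076 and 0.1). They lost them without TGFb1 replicate 1 too (0.062 and 0.064). Aldh3a1 lost its call without untreated replicates 1 and 3 (0.073 and 0.052), and Ctgf without untreated replicate 3 (0.054). With limma-voom the adjusted p of Col1a1 was 0.055. All fits with a library left out ignored the pairs, and the blocked fit was not repeated that way. With the pairs as a block and every library kept, the adjusted p was 3.9e-05 for Wisp1, 3.9e-06 for Ctgf and 0.0018 for Cyr61. In the same fit it was 3.6e-05 for Col1a1 and 0.00056 for Aldh3a1.

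**Figure D1:**
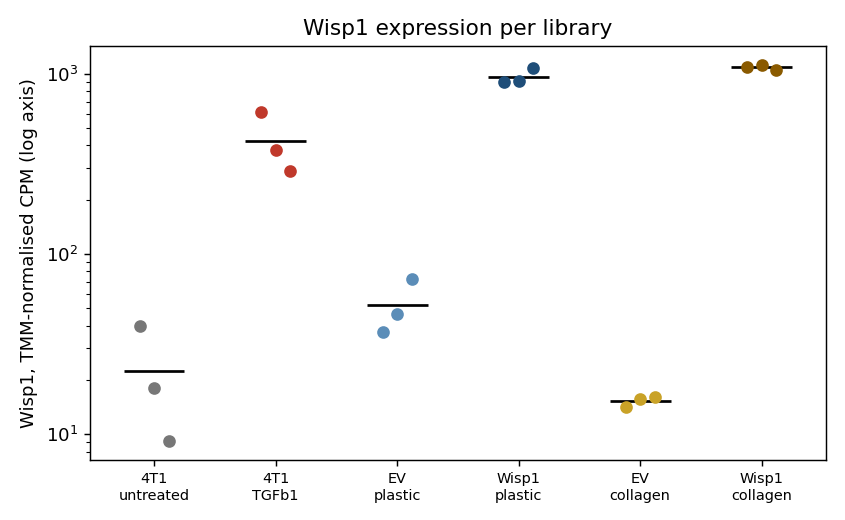
Wisp1 expression in each of the 18 libraries, in TMM-normalised CPM on a log axis, by group; points are libraries and horizontal bars the group means. Group means ran from 15.3 CPM in EV on collagen to 1090 CPM in Wisp1 on collagen, with 425 CPM in parental cells given TGFb1.

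TGFb1 raised its own transcriptional programme: of 17 TGF-beta and SMAD target genes 11 rose and 0 fell (median log2 change 1.48). This list and the basal list held with an estimated correlation, though not with the pairs as a block as well, where 2 residual degrees of freedom were left. The interferon, DNA replication, mitotic and YAP and TAZ lists did not hold with an estimated correlation (adjusted p = 0.24, 0.19, 0.38 and 0.21). Of the TGF-beta and SMAD targets, Pmepa1 and Junb rose 3.63-fold and 4.04-fold (adjusted p = 0.0014 for both). Basal and squamous epithelial genes rose, 6 of 10, among them Sfn 10.7-fold (242 ± 52 against 22.3 ± 0.96 CPM) and the laminin chain gene Lamb3 5.78-fold. Interferon response genes rose as well, 11 of 27, with Oasl2 4.32-fold, Gbp2 3.54-fold and the RNA sensor gene Ddx58 2.02-fold higher. DNA replication genes fell, 16 of 26, with Ccne2 2.11-fold and Rfc4 2.1-fold lower, and of 23 mitotic genes 6 fell, Mki67 1.63-fold and Top2a 1.58-fold among them. Of 19 YAP and TAZ target genes 9 rose and 0 fell, including Gadd45b 3.67-fold and Nuak2 2.32-fold.

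In camera tests of 29 lists, 16 passed the threshold, 12 higher and 4 lower. The adjusted p was 2.3e-26 for TGF-beta and SMAD targets and 5.5e-15 for basal genes. Both held with an estimated correlation (0.016 each), but not with the pairs as a block as well (0.28 each). That blocked fit left 2 residual degrees of freedom to estimate a correlation from, and 0 of the 29 lists held that way. Of 17 SMAD target genes, 17, 16 and 16 were higher in the 3 pairs. Of the basal genes also tested in the stable lines, 8 of 9 were higher in each pair. The camera adjusted p was 6.2e-18 for DNA replication (0.19 with an estimated correlation), 3.1e-12 for interferon (0.24), 1.1e-07 for mitosis (0.38) and 1.8e-06 for YAP and TAZ targets (0.21). With larger p-values, the lists that were higher were antigen presentation (5 of 18 rose, adjusted p = 1.7e-05, or 0.19 with an estimated correlation), fibroblast markers (4 of 9, median log2 change 1.69, 0.00013, or 0.16), matrix genes (7 rose and 1 fell of 23, 0.00056, or 0.18), matrix proteases (4 rose and 1 fell of 23, 0.0012, or 0.4), mesenchymal genes (4 rose and 1 fell of 13, 0.01, or 0.19) and collagen crosslinking genes (5 of 17, 0.01, or 0.19). Collagen receptor and focal adhesion genes (8 rose and 2 fell of 22, adjusted p = 0.03, or 0.4 with an estimated correlation) and p53 targets (2 of 18 rose, 0.039, or 0.19) were higher. Luminal genes (3 of 9 fell, adjusted p = 0.01, or 0.19 with an estimated correlation) and NRF2 genes (1 rose and 3 fell of 21, 0.036, or 0.19) were lower. Adjusted over the list alone, 14 SMAD target, 18 interferon and 26 DNA replication genes passed. With the pairs as a block, crosslinking (0.08) and NRF2 genes (0.054) missed the threshold, and CCN genes (4e-06 against 0.052) and immediate early genes (0.025 against 0.088) passed it. In that fit 23 of 23 mitotic and 26 of 26 DNA replication genes fell, and 25 of 27 interferon and 17 of 18 antigen presentation genes rose. Matrix genes then had 12 higher and 6 lower, proteases 9 and 6, crosslinking genes 10 and 3, mesenchymal genes 5 and 2, YAP and TAZ targets 11 and 3, basal genes 8 and 1, fibroblast markers 5 and 1, p53 targets 7 and 1, NRF2 genes 3 and 10 and luminal genes 1 and 5. Not past it were Wnt targets (2 rose and 3 fell of 12, adjusted p = 0.1), cholesterol synthesis (0.16), actin and SRF genes (0.16), leukocyte markers (0.17), ATF4 genes (0.3; median 0.03, mean −0.14), the unfolded protein response (0.79), histones (0.79), NF-kB (0.86), and BMP, epithelial and hypoxia genes (0.99 each). Without untreated replicate 2 the adjusted p of Top2a was 0.065, of Mki67 0.091 and of Ccne2 0.056, and without TGFb1 replicate 2 it was 0.052, 0.058 and 0.058; Mki67 also reached 0.068 without untreated replicate 1, 0.066 without untreated replicate 3 and 0.06 without TGFb1 replicate 3.

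**Figure D2:**
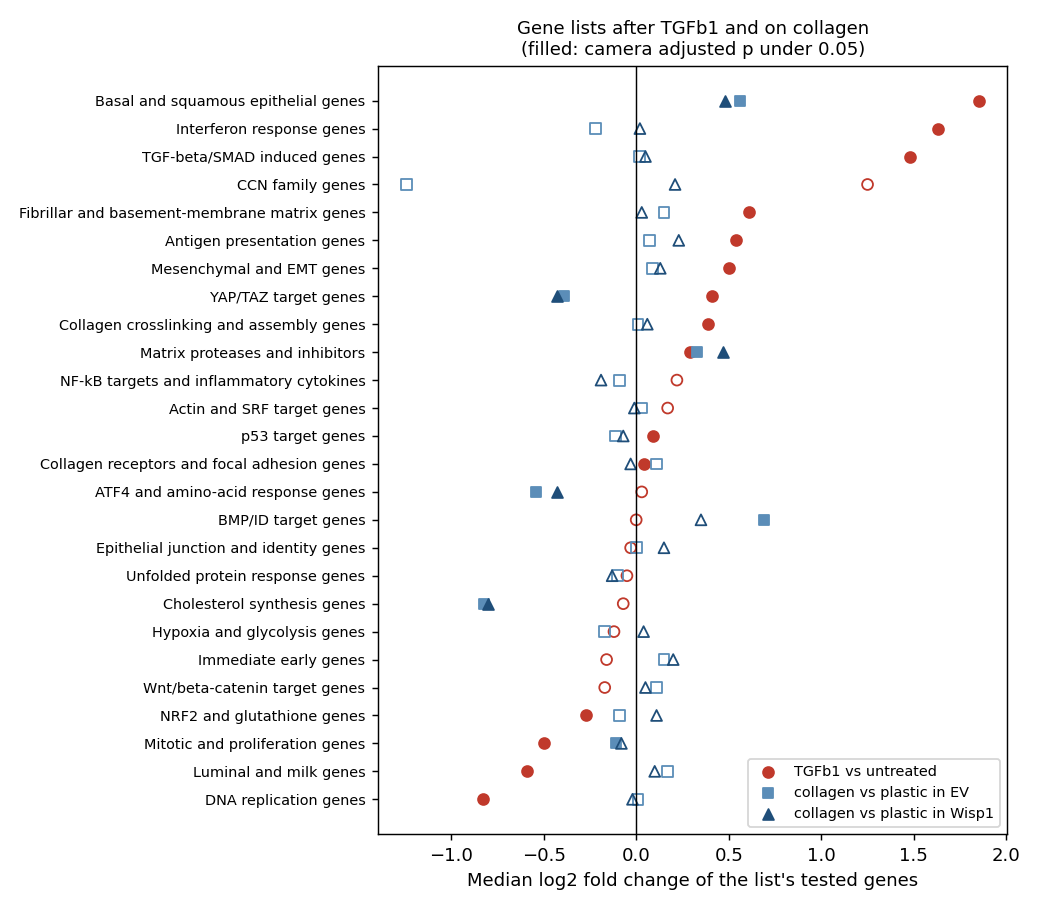
Median log2 fold change of the tested genes of each pathway list after TGFb1 (circles) and on collagen against plastic in EV (squares) and Wisp1 cells (triangles), filled where the camera adjusted p was under 0.05. TGF-beta and SMAD targets reached 1.48 after TGFb1, and cholesterol synthesis genes −0.82 on collagen in EV and −0.8 in Wisp1 cells.

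The second comparison asked what Wisp1 overexpression changed on plastic. Wisp1 itself was 18.5-fold higher in the Wisp1 line, at 957 ± 95 against 51.7 ± 18 CPM (n = 3 per group, log2 change 4.21 ± 0.21 SE, adjusted p = 3.1e-05). The counts cannot separate vector transcripts from the endogenous gene. The 1 other called gene, BC068157, chosen after its values were seen, had 9 to 23 counts per library against 1 to 2 in EV (adjusted p = 0.03). The CCN genes Ctgf (log2 change −0.12, adjusted p = 0.94) and Wisp2 (1.09, 0.82) were not called, nor were Cdh1 (−0.09, 0.83), Epcam (−0.22, 0.84), Vim (0.16, 0.79) or Fn1. The median log2 change of 21 unfolded protein response genes, which serve protein folding in the endoplasmic reticulum, was 0.13; none was called, and the list passed in camera (adjusted p = 2.1e-13) but not with an estimated correlation (0.16).

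Of 13953 genes tested on plastic, 2 rose and 0 fell by edgeR, and 822 had an unadjusted p under 0.05 where 698 were expected; DESeq2 called 18 and limma-voom 2. Fitted to only the 6 libraries on plastic, no gene was called by edgeR and Wisp1 had an adjusted p of 0.16. Leaving out a library gave 1 call, except 2 without Wisp1 replicate 1. The count was 2 with the planned block over all 4 groups and 440 (290 higher, 150 lower, median fold 1.11) with a block within each substrate, which was chosen after the data were seen. The latter fit gave 2501 genes with an unadjusted p under 0.05. In that fit Epcam was 1.17-fold lower (adjusted p = 0.0045), and Vim passed too (0.035). Of 29 lists, 9 passed in camera. CCN genes (adjusted p = 1.3e-14) and Wnt targets (6.2e-10) held with an estimated correlation (0.003 and 0.024), but both contain Wisp1, and Wnt targets without it reached 0.2. Of the unfolded protein response genes 10 passed adjusted over the list alone. The other 6 lists had larger p-values. Leukocyte markers (median log2 change 0.44, adjusted p = 0.0072, or 0.74 with an estimated correlation), actin genes (0.06, 0.018, or 0.78) and BMP targets (0.24, 0.045, or 0.78) were higher. Epithelial genes (median log2 change −0.05, adjusted p = 0.0099, or 0.78 with an estimated correlation), fibroblast markers (−0.16, 0.032, or 0.18) and ATF4 genes (−0.1, 0.033, or 0.78) were lower.

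On collagen Wisp1 was 70.7-fold higher in the Wisp1 line, at 1090 ± 33 against 15.3 ± 1.1 CPM (n = 3 per group, log2 change 6.14 ± 0.23 SE, adjusted p = 2.1e-06). The lymphocyte receptor gene Ly9 rose 1.54-fold, from 10.6 ± 0.43 to 16.3 ± 0.51 CPM (adjusted p = 0.0031), the adhesion receptor gene Gpr116 1.63-fold (10.2 ± 1.2 against 6.28 ± 0.34 CPM, adjusted p = 0.015) and the membrane transporter gene Xk 1.5-fold (adjusted p = 0.021). Epb4.1l4a, a cytoskeletal adaptor gene, was 1.45-fold lower (7.7 ± 0.42 against 11.2 ± 0.62 CPM, adjusted p = 0.015). The remaining 5 calls were chosen after their values were seen. BC068157 (15 to 18 counts per library against 1 to 2 in EV, adjusted p = 0.0053) and Chrdl1 (11 to 20 against 0 to 3, 0.035) were higher. Spna1 (2 to 3 against 19 to 41 counts, adjusted p = 0.0031), Iqgap2 (1.73-fold, 0.0045) and Cadm2 (adjusted p = 0.0058) were lower; Cadm2, an adhesion gene, had 22 to 30 counts in EV and 0 in each Wisp1 library, at least 7.4-fold lower with a floor of 3 counts per library. No other panel gene was called. Wisp2 passed with the block within each substrate (adjusted p = 0.048), at low expression. It had 0.612 ± 0.34 against 0.291 ± 0.047 CPM in EV, or 18 to 82 against 19 to 23 counts per library.

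By edgeR 10 genes were called on collagen, 6 higher and 4 lower, 5 of them by at least 2-fold, and 707 had an unadjusted p under 0.05 where 698 were expected. DESeq2 called 40, and edgeR 32 with no filter, 6 with the stricter filter, 2 with only the 6 libraries on collagen and 4 with all 18. The planned block gave 18 and the block within each substrate 358 (median fold 1.14, and 2252 genes with an unadjusted p under 0.05). The count was 5 without EV replicate 3 and 6 without Wisp1 replicate 2. The call of Gpr116 ended without EV replicate 2 (adjusted p = 0.084), EV replicate 3 (0.15) and Wisp1 replicates 1 and 2 (0.052 and 0.09). That of Xk ended without EV replicates 2 and 3 (0.17 and 0.16) and Wisp1 replicates 1, 2 and 3 (0.083, 0.09 and 0.058), and that of Epb4.1l4a without EV replicate 3 (0.13) and Wisp1 replicates 2 and 3 (0.09 and 0.061). With only the 6 libraries on collagen the adjusted p was 0.14 for Gpr116 and 0.12 for Xk and Epb4.1l4a, with all 18 libraries in one fit it was 0.46, 0.45 and 1, and Xk reached 0.06 with thinned libraries. Over all alternatives it ran from 1.8e-06 to 0.46 for Gpr116, 2.8e-05 to 0.45 for Xk and 3.1e-06 to 1 for Epb4.1l4a. Of 29 lists, 5 passed in camera: CCN genes (adjusted p = 3.2e-28, held with an estimated correlation at 0.00032) and Wnt targets (1.1e-07, or adjusted p = 0.051 with an estimated correlation), both with Wisp1 in them, the unfolded protein response (3e-16, or 0.097), and antigen presentation and interferon genes (1.1e-07 each, or 0.54). Wnt targets without Wisp1 reached 0.81. With the planned block Wnt targets held with an estimated correlation (0.011) and matrix genes passed in camera (0.044 against 0.05). No unfolded protein response gene was called over all genes and 9 were adjusted over the list alone, with a median log2 change of 0.18.

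In the fit blocked within each substrate, chosen after the data were seen, 11 of 21 unfolded protein response genes rose on plastic and 12 on collagen, and the list held with an estimated correlation (adjusted p = 0.032 and 0.024). Hsp90b1, the chaperone of the endoplasmic reticulum lumen, rose 1.17-fold on plastic (adjusted p = 2e-05) and 1.18-fold on collagen (9e-06), and the lectin chaperone gene Calr 1.27-fold and 1.16-fold (1.4e-06 and 0.00019). The disulfide isomerase genes Pdia4 and Pdia6 rose 1.16-fold and 1.17-fold on plastic and 1.19-fold each on collagen, and the BiP gene Hspa5 1.16-fold and 1.09-fold. These members were chosen after their values were seen. The median member was higher in 6 of 6 pairs, by 0.19, 0.14 and 0.15 (log2) on plastic and 0.18, 0.18 and 0.12 on collagen. On plastic the same fit also put collagen receptor (adjusted p = 0.014, or 0.36 with an estimated correlation), antigen presentation (0.0082, or 0.52) and NF-kB genes (0.045, or 0.52) past the threshold, and CCN genes reached 0.055 with an estimated correlation. On collagen it added basal genes (adjusted p = 0.043, or 0.7 with an estimated correlation).

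**Figure D3:**
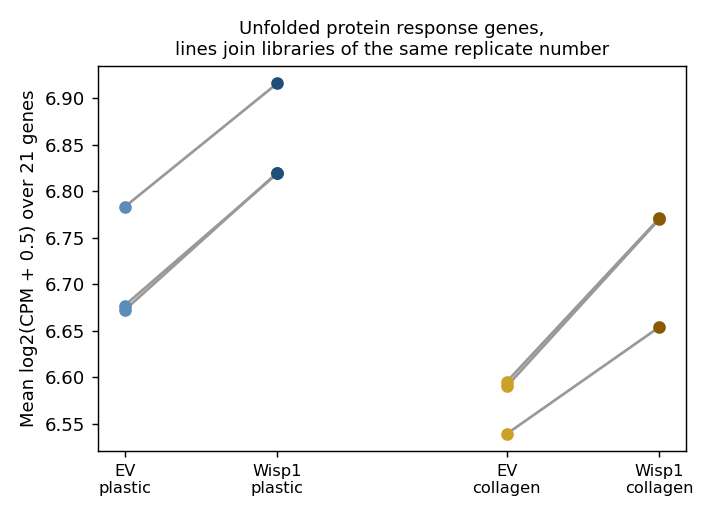
Mean log2(CPM + 0.5) over 21 unfolded protein response genes in each EV and Wisp1 library on plastic and on collagen, with lines joining libraries of the same replicate number. Each of the 6 Wisp1 libraries lay above the EV library of its number, from 6.654 to 6.916 against 6.539 to 6.783.

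Whether the effect of Wisp1 differed between substrates was tested as an interaction. Wisp1 itself was higher on both, and the difference of 1.94 (log2) had an adjusted p of 0.43, the smallest of any gene. No gene was called by edgeR (410 with an unadjusted p under 0.05, 698 expected); DESeq2 and limma-voom called 1 each, and edgeR 1 without EV plastic replicate 1 or replicate 3. Ly9 and Gpr116, called on collagen only, had interaction adjusted p of 0.97 each, so no difference between substrates was shown for them. The block within each substrate gave 70 genes, with the Wisp1 effect higher on collagen for 29 and lower for 41. In that fit 2040 genes had an unadjusted p under 0.05, and 626 had with the planned block. Across genes, which are not independent replicates, Wisp1 effects on plastic and collagen correlated at 0.219 without Wisp1 itself (Spearman's rho 0.058 with it), and at 0.085 among genes with a mean log2 CPM of at least 1.

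The next comparisons asked what growth on collagen changed in each line. In EV cells Fam102a rose 4.84-fold, from 3.45 ± 0.21 to 16.4 ± 1 CPM (n = 3 per group, log2 change 2.27 ± 0.08 SE, adjusted p = 1.6e-09), and in Wisp1 cells 4.77-fold (2.3e-09). The stromelysin gene Mmp3 rose 4.65-fold in EV (66.4 ± 20 against 14.5 ± 3 CPM, adjusted p = 0.00024) and 4.87-fold in Wisp1 cells, and the pentraxin gene Nptx1 4.47-fold and 4.75-fold. Ctgf was 4.41-fold lower in EV (43.6 ± 2.5 against 196 ± 53 CPM, adjusted p = 7e-05) and 4.06-fold lower in Wisp1 cells (8.8e-05). Endogenous Wisp1 in EV cells was 3.3-fold lower on collagen (15.3 ± 1.1 against 51.7 ± 18 CPM, adjusted p = 0.00013). Ctsw, a cathepsin gene, was 4.95-fold and 5.03-fold lower, and Ngef rose 3.89-fold and 4.42-fold. Gpnmb rose 3.67-fold in EV and Xdh 4.48-fold in Wisp1 cells. Nov rose 3.07-fold and 5.06-fold, Cyr61 was 2.36-fold and 2.68-fold lower, Tgfb1 rose 1.66-fold and 1.75-fold, Tgfb2 was 2.83-fold and 2.39-fold lower, and Cdh1 1.24-fold and 1.18-fold lower. In Wisp1 cells the level of Wisp1 did not pass (log2 change 0.21 ± 0.18, adjusted p = 0.38, or 0.027 in a fit of those 6 libraries alone).

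Smaller panel changes on collagen depended on single libraries. Fn1 was lower in both lines (adjusted p = 0.027 and 0.044), but in EV it missed the threshold without plastic replicate 3 (0.097) and collagen replicates 1 and 3 (0.1 and 0.07). In Wisp1 cells Fn1 missed it without plastic replicates 1 and 3 (0.055 and 0.15) and collagen replicates 1 and 3 (0.18 and 0.12), and without a filter it reached 0.095 and 0.13. Snai1 was higher in EV (adjusted p = 0.014, or 0.072 without plastic replicate 2 and 0.071 without collagen replicate 2) and reached 0.062 in Wisp1 cells (0.026 without plastic replicate 3 and 0.046 without collagen replicate 3). Tgfb3 was higher in Wisp1 cells (adjusted p = 0.042, or 0.16 and 0.14 without plastic replicates 1 and 2, 0.19 without collagen replicate 1 and 0.059 with the planned block) and not called in EV (0.62). Vim, Epcam, Smad7, Zeb1, Col1a1 and Wisp2 were called in neither line. Smad7 passed in EV without plastic replicate 3 (0.0087) and Zeb1 without plastic replicate 1 (0.036). In Wisp1 cells Col1a1 passed without collagen replicate 2 (0.017), and Wisp2 without collagen replicate 2 (0.048) or 3 (0.016). With all 18 libraries in one fit, Cdh1 missed the threshold in EV and Wisp1 cells (0.09 and 0.17) and Tgfb1 in EV (0.055).

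Cholesterol synthesis genes fell on collagen, 21 of 23 in each line (median log2 change −0.82 in EV and −0.8 in Wisp1 cells). With an estimated correlation neither this list nor any other passed on collagen in either line (adjusted p = 0.32 in EV and 0.3 in Wisp1 cells for cholesterol synthesis). Hsd17b7 was 2.03-fold and 2.21-fold lower, and Nsdhl, a sterol dehydrogenase gene, 1.93-fold lower in EV. ATF4 targets of amino acid and one-carbon metabolism fell, 21 and 15 of 25, with Mthfd2 1.65-fold and 1.69-fold, Psat1 1.45-fold and 1.52-fold and Psph 1.59-fold and 1.48-fold lower. Of 19 YAP and TAZ targets 10 fell and 3 rose in EV, and 11 fell and 2 rose in Wisp1 cells; Gadd45b was 2.8-fold and 2.72-fold lower and Ankrd1 1.84-fold and 1.93-fold, whereas Axl rose 1.17-fold in EV and Arhgef17 1.2-fold in Wisp1 cells. Matrix protease genes rose, 12 of 23 in each line against 5 and 4 that fell. The urokinase receptor gene Plaur rose 2.42-fold in EV (170 ± 2 against 71.7 ± 5.6 CPM) and 2.04-fold in Wisp1 cells, Timp2 1.94-fold and 2.07-fold, and Mmp14, a collagenase of the cell surface, 1.85-fold and 2.03-fold. Of the basal list, Col17a1, a collagen gene of epithelial attachment, rose 2.62-fold and 1.97-fold, the integrin genes Itgb4 1.83-fold and 1.98-fold and Itga6 1.54-fold and 1.4-fold, while the keratin genes Krt14 and Krt17 were lower, Krt14 1.52-fold in EV and Krt17 1.74-fold in Wisp1 cells (adjusted p = 0.021). The call of Krt17 ended without plastic replicates 1 and 3 (0.06 and 0.072) and collagen replicate 1 (0.13), without a filter (0.075), with DESeq2 (0.093) and with only those 6 libraries (0.053), and its adjusted p over all alternatives was 0.017 to 0.44. With all 18 libraries in one fit, the adjusted p was 0.08 and 0.17 for Itga6 in EV and Wisp1 cells, 0.18 for Krt14, 0.3 for Axl and 0.12 for Arhgef17.

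On collagen 5095 of 13953 genes were called in EV (2678 higher, 2417 lower) and 5641 in Wisp1 cells (2974 higher, 2667 lower), or 1629 and 2071 with all 18 libraries in one fit, against 698 expected at an unadjusted p under 0.05 and 6360 and 6859 found. The median size of the called changes was 0.3 (log2) in each line, and 376 and 400 genes changed by at least 2-fold. Both lines shared 2177 higher and 1907 lower genes (570.8 and 462 by chance) and 1 opposite, and the log2 changes correlated at 0.809 across genes. Libraries on plastic and on collagen carry different sample-code series in the labels, so substrate and a possible preparation batch cannot be told apart. The mitochondrial share of counts was 0.567 to 0.617% on plastic and 0.766 to 1.07% on collagen. Camera gave an adjusted p of 1e-24 in EV and 3.6e-23 in Wisp1 cells for cholesterol synthesis, 2.3e-10 and 2e-07 for ATF4 genes (0.47 and 0.88 with an estimated correlation), 1.3e-06 and 2e-07 for YAP and TAZ targets (0.47 and 0.79), 2.4e-06 and 2e-06 for proteases (0.32 and 0.3) and 0.0055 and 0.011 for basal genes (0.47 and 0.86). In EV, BMP targets were higher (5 of 8 rose, adjusted p = 0.022, or 0.67 with an estimated correlation), with Id2 2.28-fold, Atoh8 4.28-fold and Id4 1.77-fold higher (0.052 for Id4 with all 18 libraries in one fit), and mitotic genes were lower (11 fell and 1 rose of 23, 0.035, or 0.67 and 0.051 with the block). In Wisp1 cells these lists gave 0.16 and 0.1; Aurka, a mitotic kinase gene, was 1.25-fold lower there (adjusted p = 5.8e-05, or 0.12 with all 18 libraries). The other lists did not pass in either line. Among those, 9 of 21 unfolded protein response genes fell and 2 rose in each line (5 rose in Wisp1 cells with the planned block), and of 21 matrix genes 8 rose and 5 fell.

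**Figure D4:**
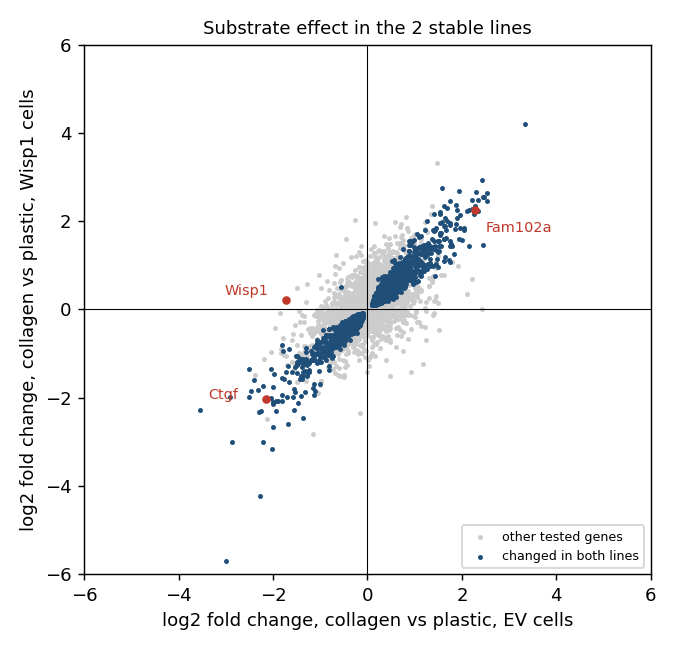
Log2 fold change on collagen against plastic in EV cells (horizontal) and in Wisp1 cells (vertical), 1 point per tested gene, dark where the gene was called in both lines, with Fam102a, Ctgf and Wisp1 in red. The changes correlated at 0.809 across genes, and Wisp1 was at −1.72 in EV and 0.21 in Wisp1 cells.

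TGFb1 genes were then followed in the other comparisons, which share no library with the TGFb1 comparison. Across genes the TGFb1 and Wisp1 effects correlated at −0.044 on plastic and 0.003 on collagen. The 419 genes raised at least 2-fold by TGFb1, Wisp1 left out, were lower in the Wisp1 line on plastic (median log2 change −0.057, 32.5% positive, camera p = 0.00029), but not with an estimated correlation (0.38), and on collagen they gave 0.08. None of the 419 was called on either substrate. In the fit blocked within each substrate 4 of them rose and 20 fell on plastic (8.7 and 4.5 expected; camera p = 2e-05, or 0.12 with an estimated correlation). On collagen 14 rose and 3 fell in that fit (6.8 and 3.9 expected; camera p = 0.047, or 0.4 with an estimated correlation). The 288 genes lowered by TGFb1 gave 0.12 on plastic and were higher on collagen (camera p = 0.023, or 0.56 with an estimated correlation and 0.7 for genes lowered by any fold); 2 of them were called there, both higher, and none on plastic. In the fit blocked within each substrate 13 of the 288 rose and 3 fell on plastic (6 and 3.1 expected; camera p = 0.11), and 13 rose and 1 fell on collagen (4.7 and 2.7 expected; 0.0065, or 0.32 with an estimated correlation). On collagen against plastic in EV, 129 of the 288 rose and 13 fell (camera p = 1.9e-12, or 0.093 with an estimated correlation and 0.044 with the block too), and in Wisp1 cells 143 rose and 18 fell (7.5e-12, or 0.11). Of the 419, 58 rose and 134 fell in EV (camera p = 0.00025, or 0.38 with an estimated correlation), and 72 rose and 103 fell in Wisp1 cells (0.077). Of the 809 genes raised by any fold, 182 rose and 199 fell in EV, and 217 rose and 171 fell in the Wisp1 line. As a set these did not pass in camera, at p = 0.43 in EV (lower, or 0.83 with an estimated correlation) and 0.52 in the Wisp1 line (higher, or 0.86). Among the panel genes named above that were called in both, Wisp1, Ctgf, Cyr61, Tgfb2 and Fn1 rose with TGFb1 and fell on collagen in EV cells, Nov did the reverse, and Snai1 rose in both.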

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

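The interaction tests of the gene lists were planned, and their repeats without Wisp1 and with a block within each substrate were chosen after the results were seen. In camera tests of the interaction between the Wisp1 vector and the substrate 4 lists passed the threshold. The Wisp1 effect was higher on collagen than on plastic for interferon response genes (adjusted p = 0.00081), CCN genes (0.0014) and antigen presentation genes (0.04). The Wisp1 effect was lower on collagen for leukocyte markers (0.04). With an estimated correlation none of these lists passed: the adjusted p was 0.28 for CCN genes and 0.96 for the other 3, and fry gave no list past the threshold. The CCN list contains Wisp1 itself. With Wisp1 left out of the lists that hold it, interferon genes reached 0.00078 and antigen presentation genes and leukocyte markers 0.051 each, and the CCN list was then too short to test. With the planned replicate block interferon genes reached 0.00011 and CCN genes 0.00036, and antigen presentation genes and leukocyte markers 0.074 each. With a block within each substrate leukocyte markers reached 0.17, and 5 further lists passed: BMP targets (0.00044), ATF4 (0.0018), epithelial (0.009), DNA replication and hypoxia genes (0.048 each), none with an estimated correlation (0.73 to 0.86). No member of the interferon list was called in the interaction without a block, and 1 was with the block within each substrate. Groups of 3 libraries were too small for a check of single libraries that stand apart. No technical or biological explanation of these results was tested.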

How the results depend on the processing

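The block within each substrate, the averages over both substrates, the thinned libraries, the lists without Wisp1 and the limit on mean expression were chosen after the data were seen, and the cause of a change was not tested unless stated. Over all alternatives the named genes gave 2642 values, of which 2523 kept their side of the threshold, 104 lost their call and 15 gained one. No called value changed direction, and 59 values that were not called changed sign. The count after TGFb1 (1645) was 2910 with DESeq2, 6672 with the replicate block, 4865 with all 18 libraries in one fit, 858 at 2-fold or more, and 380 to 1430 with a library left out. Wisp1 on plastic (2) gave 18 with DESeq2, 1 with the stricter filter, 0 with only the 6 libraries compared, 1 with all 18 libraries, 440 with the block within each substrate, 1 with thinned libraries and 1 to 2 with a library left out; the stricter filter no longer tests BC068157. Wisp1 on collagen (10) gave 32 with no filter, 6 with the stricter one, 40 with DESeq2, 18 with the replicate block, 2 with only the 6 libraries, 4 with all 18, 358 with the block within each substrate, 5 at 2-fold or more and 5 to 11 with a library left out. The interaction (0) gave 1 with DESeq2 and with limma-voom, 70 with the block within each substrate and 0 to 1 with a library left out. Collagen in EV (5095) gave 1629 with all 18 libraries, 376 at 2-fold or more and 3849 to 4598 with a library left out. Collagen in Wisp1 cells (5641) gave 2071, 400 and 4450 to 5443 in that order. Averaged over both substrates, Wisp1 called 27 genes, or 654 with the block. With an estimated correlation the lists past the threshold were 2 after TGFb1 (16), 2 for Wisp1 on plastic (9) and 1 on collagen (5). They were 0 for collagen in either line and for the interaction, and 0 after TGFb1 with the pairs as a block as well. With fry the lists past the threshold were 15 after TGFb1 and 2 on plastic and on collagen for Wisp1. They were 14 and 12 for collagen in EV and Wisp1 cells, and 0 for the interaction. With the block within each substrate fry gave 7 for Wisp1 on plastic, 4 on collagen and 0 for the interaction. The interaction (4) gave 2 with the replicate block, 8 with the block within each substrate and 1 without Wisp1, and Wisp1 on collagen gave 3 lists without Wisp1. Genes raised by TGFb1 had p = 0.38 on plastic with an estimated correlation and 0.4 with fry, and genes lowered by it had 0.7 on collagen at any fold, 0.56 with an estimated correlation and 0.55 with fry. The correlation of Wisp1 effects between substrates was 0.085 among genes with a mean log2 CPM of at least 1. The replicate block set in advance changed no other call of a named gene, or of a list or TGFb1 gene set in camera, than those given with the results. In simulated data the TGFb1 fit without a block recovered 20% of 2-fold changes, and its fit with the pairs as a block was not simulated. Genes with a few counts per library, such as Cadm2 on plastic, allow no fold at this depth.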

Other observations

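The repeats of the Wisp1 comparisons with a block within each substrate, and every gene named in this paragraph, were chosen after the results were seen, as were the tests of batch and of line difference below. In that fit the small changes went beyond chaperones. On collagen 8 of 18 antigen presentation genes rose (camera adjusted p = 1.5e-14, or adjusted p = 0.12 with an estimated correlation), among them the immunoproteasome subunit gene Psmb8 (1.28-fold, adjusted p = 2.6e-05) and the light chain gene B2m (1.12-fold, 0.0012). The chaperone gene Calr is also among the 8 and belongs to the unfolded protein response list too, so the 2 lists are not independent. On plastic 4 of 27 epithelial genes fell (0.00014, or 0.52 with an estimated correlation): the splicing factor gene Esrp1 was 1.2-fold lower there (adjusted p = 0.001) and 1.19-fold lower on collagen (0.00078), and the claudin genes Cldn4 and Cldn7 1.3-fold and 1.27-fold lower on plastic. The BMP targets Id1 and Id3 rose 1.31-fold and 1.21-fold on plastic, and Id3 differed between substrates (interaction log2 −0.28, adjusted p = 0.009). The 2 substrates shared 31 genes higher (4.7 by chance) and 16 lower (1.4), with 3 opposite.

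Some scarce transcripts, chosen after their values were seen, differed in counts between the lines on both substrates. Col3a1, a fibrillar collagen gene, had 28 to 61 counts per library in EV and 0 to 5 in Wisp1 cells on plastic, and 8 to 23 against 0 to 2 on collagen. Spna1 had 7 to 18 against 1 to 3 counts on plastic, and Chrdl1 1 to 4 in EV against 10 to 13 in Wisp1 cells.

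The unfolded protein response list passed in camera as higher in the Wisp1 line on both substrates. Without a block no member was called, and with an estimated correlation the adjusted p was 0.16 on plastic and 0.097 on collagen; it held there only in the fit blocked within each substrate. The mean log2 CPM of the list was 6.672, 6.677 and 6.783 in EV and 6.82, 6.819 and 6.916 in Wisp1 cells on plastic, and 6.59, 6.595 and 6.539 against 6.77, 6.771 and 6.654 on collagen. The mean difference of 0.149 had an exact permutation p of 0.005 within substrates, the smallest that 400 permutations can give. The permutation moved labels freely within each substrate and did not keep the pairs by replicate number. Swapping within the pairs has 32 ways and cannot give so small a p. Apart from CCN genes, which hold Wisp1, none of the 29 lists had a smaller camera p on either substrate. The list was therefore singled out on the same data. Its median lay above 100% of 10000 random lists matched on expression, which argues against a trend with expression level, though random lists carry no correlation between members. A difference between the 2 cell lines that does not come from Wisp1, such as a clonal one, stays open: the smaller of the list's medians was 0.13, and with 1 line per vector it cannot be told apart from an effect of Wisp1.

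The collagen response of EV cells covered 5095 genes. Depth as its whole cause is argued against by libraries thinned to equal totals, which gave 4708, and GC content and length by offsets for them, which gave 4761 against 5043 on the same genes. A batch shared by the collagen libraries could give the correlation of 0.809 between the lines as well as collagen could, and because the labels set plastic and collagen libraries apart it cannot be told apart from the substrate.

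Other splits of the libraries were counted for each result. The 6 libraries of 1 comparison make 10 splits, too few for a share under 0.05: the real split gave 1645 genes after TGFb1, 2 and 10 for Wisp1 on plastic and collagen, 5095 and 5641 for collagen in EV and Wisp1 cells and 0 for the interaction, and the highest other gave 0 in each. With pairs kept, 4 ways are too few as well: 6672 against 0 for TGFb1, 440 against 2 for Wisp1 on plastic and 358 against 0 on collagen. For Wisp1 averaged over both substrates there were enough ways for a share under 0.05. With pairs kept, 1 of 32 ways of swapping vectors gave as many as the real 654, with 81 the highest other. Without the block 1 of 100 drawn splits gave as many as 27, with 2 the highest other. This argues against spread between cultures as the whole cause of those counts. The averaging and the pairs were chosen after the data were seen, so chance is not excluded. With 1 line per vector, the splits cannot tell Wisp1 from another difference between the lines.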
